A study of Mus musculus with 6 samples.

How the data were processed

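Total RNA from the lungs of wild-type C57BL/6 mice aged 9 to 10 weeks was sequenced by Illumina RNA sequencing, in 6 libraries. The CS group (3 libraries) came from mice exposed to cigarette smoke in 2 sessions of 75 min a day, on 5 days of each of 4 weeks. The SS-31H_CS group (3 libraries) came from mice that were exposed to smoke and also received SS-31, a mitochondria-targeted antioxidant peptide, at 5 mg/kg once daily. No smoke-free lungs and no lower dose of SS-31 were among the 6 libraries. The labels do not say whether each library came from a separate mouse, and every p-value assumes that it did. They give no sequencing batch, library date, sex or hour at which the lungs were taken. They give the smoke schedule for the CS group only, so equal exposure of the SS-31H_CS group could not be checked.

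The authors deposited raw read counts per Ensembl gene (55573 genes, no normalization) and FPKM for the same libraries. Per the labels, cutadapt 1.9.1, HISAT2 2.0.1, HTSeq 0.6.1 and the GRCm38 mouse genome were used, with the annotation release, the strand setting and the filters left unstated. The deposited FPKM were checked against the counts over 3310 genes with more than 1000 counts in every library: FPKM divided by count followed the library totals alone, with a largest gap of 0.33%. They hold no scaling between libraries beyond the library total.

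Gene symbols and GRCm38 coordinates were taken from GENCODE M21 by Ensembl identifier (55394 genes matched, 179 did not). Total counts ran from 15611925 to 17360052 per library, and 3 counts in a library corresponded to 0.173 to 0.192 CPM. CPM values, counts divided by library size and put on the usual common scale, were computed with the TMM-scaled library sizes.

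The SS-31H_CS libraries were compared with the CS libraries by edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) with TMM normalization, edgeR's own low-count filter (minimum count 10, minimum total 15) and Benjamini-Hochberg adjustment, two-sided. A gene was said to have changed at an adjusted p under 0.05. Log2 fold changes are SS-31H_CS over CS, so positive values are higher with SS-31. For 49 fixed gene lists (pathways, cell type markers and complexes), members were also adjusted over the list alone. This second adjustment does not control errors over the 49 lists together. A gene said to rise or fall only over its list alone did not pass the threshold for a changed gene. Members of a list can also vary together, so the number that passed is not a number of independent findings. The 46 lists with at least 5 tested members, the sex-linked list being left out, were tested by limma's camera (limma 3.58.1) on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera with a correlation estimated per list and fry, a rotation test of each list by itself, were run beside it.

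The gene lists, the tests, the thresholds, the rule for naming genes and all alternatives not described as added later were chosen before the data were examined. The named genes are the 10 with the largest change in each direction among genes past the threshold with a mean CPM of at least 1 and groups that do not overlap, the 5 with the lowest p, 20 fixed genes whatever their result, and up to 4 members per called list (2 for other lists) with the lowest p. A gene named outside this rule is said to have been chosen after its values were seen.

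The alternatives were size factors by the RLE method, library size alone, no low-count filter, a filter at 1 CPM in at least 3 libraries, DESeq2 1.42.0, limma voom, edgeR with robust dispersion, limma trend on log2(FPKM + 1) and log2(FPKM + 0.1) for genes with a mean FPKM of at least 0.5 and on log2(FPKM + 1) without that filter, an absolute log2 fold change of at least 1, an adjusted p under 0.1, the replicate number as a block, and leaving out each library in turn. Leaving out the third library of both groups together, and leaving out libraries for the counts adjusted over single lists, were added after seeing the data. With 1 library left out, the 2 libraries left in a group are assumed to vary like the 3 of the other.

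The tests were checked on data simulated with the observed spread, in 5 simulations with 200 genes each made to change by 1.5-, 2- or 4-fold. Genes were drawn independently of each other, and only genes with a mean of at least 1 CPM were made to change. The shares below therefore do not cover genes that vary together, such as the ciliated cell markers (estimated correlation 0.796), or genes at lower levels. edgeR's test found 5.1% of the 1.5-fold, 58.1% of the 2-fold and 93.6% of the 4-fold genes, and 8.8% of its calls were false. The false share was 36.3% without the low-count filter, 19.6% with DESeq2 and 7.2% with voom. These found 69.9%, 69.5% and 53.3% of the 2-fold genes. Reads shared between similar genes, such as hemoglobin, immunoglobulin and MHC genes, could not be told apart from the deposited tables.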

Results

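Lung transcript levels were measured in 6 RNA sequencing libraries, 3 from mice exposed to cigarette smoke (CS) and 3 from mice exposed to smoke and given SS-31 (SS-31H_CS). The comparison addresses the effect of SS-31 on airway inflammation and oxidative stress during smoke exposure, the purpose named in the series title. Total counts were 17201819, 17360052 and 17056917 for CS replicates 1, 2 and 3, and 16880778, 15611925 and 16942014 for SS-31H_CS replicates 1, 2 and 3. A total of 16965 genes had enough counts to be tested. The first principal component held 46.4% of the variance, with CS replicate 3 at -61.3 and SS-31H_CS replicate 3 at 44.8 as its ends. Without smoke-free lungs, no background level could be set beside these values.

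With SS-31, the clock genes Dbp, Nr1d1, Nr1d2 and Per3, the cilium genes Cfap43, Ccdc17 and Ccdc151 and the club cell gene Scgb3a2 rose. The clock gene Arntl, the lipid enzyme gene Lpl, the macrophage protein gene Cd5l, the hyaluronan synthase gene Has1 and the matrix protein gene Thbs1 fell. In all, 26 genes changed at an adjusted p under 0.05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 12 higher and 14 lower. In each of the 26, the values of the groups did not overlap. Across all tested genes the groups did not overlap in 4421 (26.1%), where chance gives 10%. At an unadjusted p under 0.05 there were 3081 genes (1684 higher, 1397 lower), where chance gives 848. The number of changed genes fell whichever single library was left out, in fits that also had fewer samples. It was 1 without CS replicate 1 or SS-31H_CS replicate 2. It was 2 without CS replicate 2, SS-31H_CS replicate 1 or SS-31H_CS replicate 3, and 15 without CS replicate 3. Among the named genes, Lpl, Thbs1, Fam107a and Vstm4 passed only without CS replicate 3 of the single libraries, Has1 without CS replicate 2 or CS replicate 3, and Scgb3a2, Cfap43, Ccdc17, Ccdc151, Cd5l, Slc6a2, Leo1 and Il18r1 did not pass when any 1 of the 6 was left out. The count was 0 with the replicate number as a block, 948 by DESeq2 and 6 by limma voom. In simulated data DESeq2 gave a larger share of false calls than voom (19.6% against 7.2%). It also found more of the genes made to change (69.5% against 53.3% of the 2-fold genes). Each simulation changed 200 genes and that number was not varied, so the false share among the 948 is not known.

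**Figure D1:**
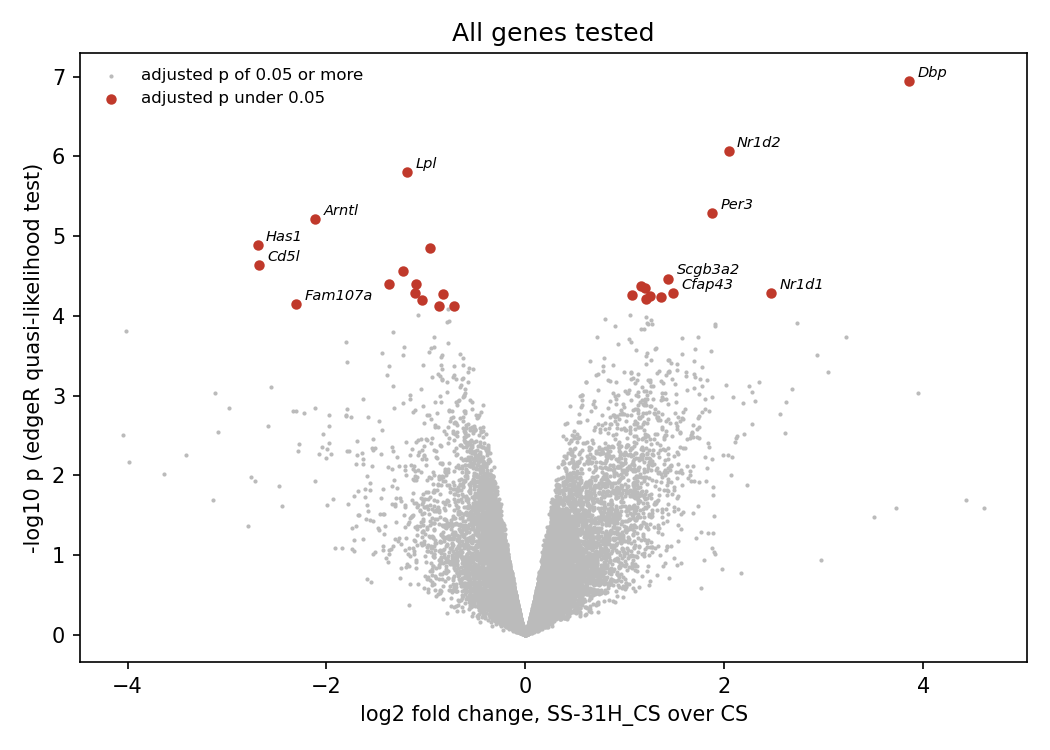
Each point is 1 of the 16965 genes tested; the horizontal axis is the log2 fold change, SS-31H_CS over CS (3 libraries each), and the vertical axis is -log10 of the unadjusted p of edgeR's quasi-likelihood test. The 26 genes with an adjusted p under 0.05 are in red, with Dbp (log2 fold change 3.86) farthest to the right among them and Has1 (-2.69) farthest to the left.

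Several clock genes changed. Dbp, a transcription factor driven by the core clock (ENSMUSG00000059824, chromosome 7, 45705088 to 45710203), rose 14.5-fold from 5.55 ± 1.28 to 80.8 ± 17.7 CPM (SD, n = 3 per group). Its log2 fold change was 3.86 (SE 0.23, adjusted p = 0.00191). The REV-ERB repressor genes Nr1d1 and Nr1d2 rose as well. Nr1d2 (ENSMUSG00000021775, chromosome 14, 18204054 to 18239127) went from 31.9 ± 0.945 to 131 ± 26.5 CPM (log2 fold change 2.04, SE 0.16, adjusted p = 0.00734), and Nr1d1 from 16.4 ± 7.53 to 91.2 ± 20.6 CPM (2.47, SE 0.32, adjusted p = 0.0467). The period gene Per3 (ENSMUSG00000028957, chromosome 4, 151003652 to 151044665) rose from 42.5 ± 7.84 to 156 ± 26.7 CPM (1.88, SE 0.18, adjusted p = 0.0207). Hlf (1.20) and Bhlhe41 (1.25) also rose. In the opposite direction, Arntl, which encodes the core activator BMAL1 (ENSMUSG00000055116, chromosome 7, 113207465 to 113314126), fell from 24.6 ± 4.84 to 5.69 ± 0.938 CPM (-2.11, SE 0.21, adjusted p = 0.0207).

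Of the 18 genes in the circadian clock list, 6 rose and 1 fell over all genes tested, and 9 rose and 5 fell adjusted over the list alone. The members moved both ways. Camera, which asks for a shift in a single direction, gave an adjusted p of 0.0503 (0.788 with an estimated correlation), and fry's test for change in either direction gave 0.00219. Dbp passed without any 1 of the 6 libraries (adjusted p 0.00323 to 0.0233). Nr1d2 passed without CS replicate 3, SS-31H_CS replicate 1 or SS-31H_CS replicate 3, and Nr1d1, Per3, Hlf and Arntl passed only without CS replicate 3 among the single libraries. Bhlhe41 did not pass when any 1 of the 6 was left out. The labels give no hour of collection, on which clock transcripts depend.

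**Figure D2:**
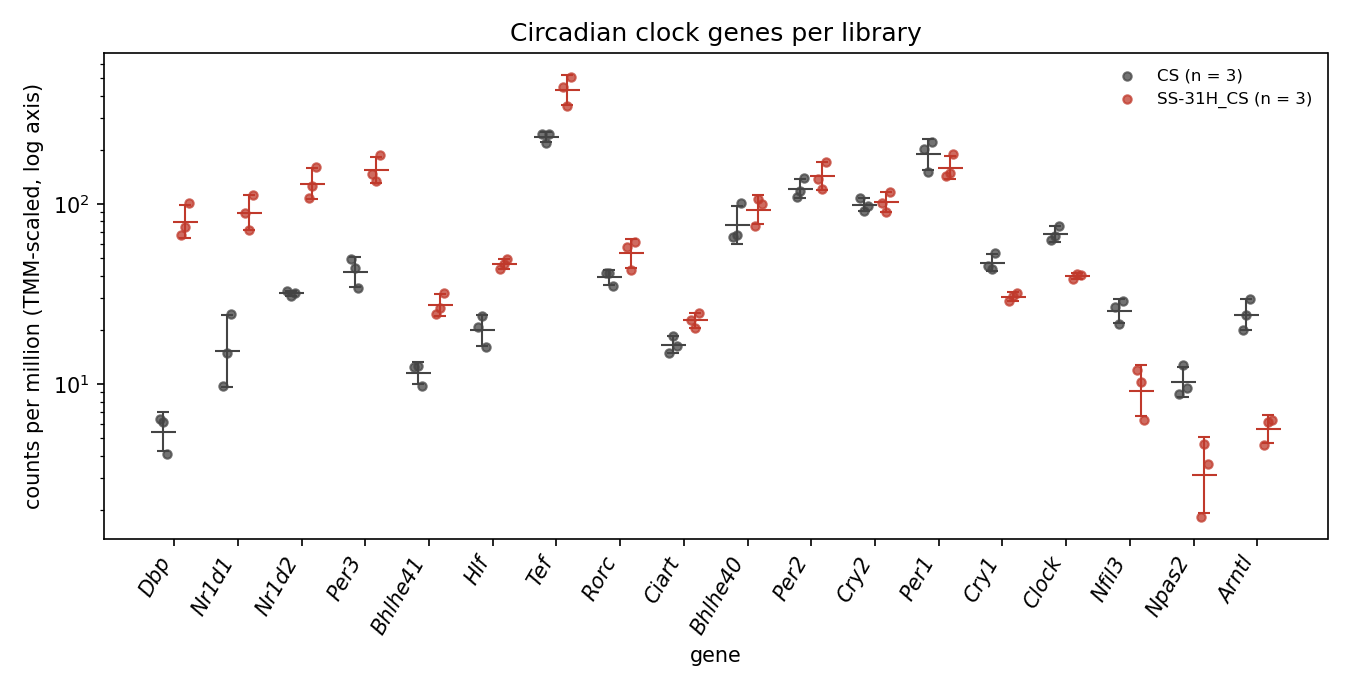
CPM (TMM-scaled, log axis) of the 18 clock genes in the 3 CS libraries (grey) and the 3 SS-31H_CS libraries (red); points are libraries, and the line and bars are the mean and SD on the log2 scale. Dbp lies between 4.08 and 6.37 CPM in CS and between 67.3 and 101 CPM in SS-31H_CS, and Arntl between 20.1 and 29.7 against 4.61 and 6.29 CPM.

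Markers of ciliated airway cells were higher as a group: 18 of 18 rose adjusted over the list alone and 0 over all genes tested by edgeR's quasi-likelihood test (18 at an unadjusted p under 0.05, 15 by DESeq2), with a median log2 fold change of 1.08 (2.11-fold). Foxj1, the master regulator of motile cilia, went from 60.5 ± 7.67 to 150 ± 44.8 CPM (log2 fold change 1.31, adjusted p = 0.0728 over all genes), and Dynlrb2, a dynein light chain gene, from 19.9 ± 3.19 to 49.3 ± 14.2 CPM (1.31, adjusted p = 0.0730). Outside the list, the cilium genes Cfap43 (24.2 ± 2.20 to 67.8 ± 17.9 CPM, 1.49, adjusted p = 0.0467) and Ccdc151 (7.62 ± 0.413 to 17.7 ± 2.36 CPM, 1.22, adjusted p = 0.0467) rose over all genes. Ccdc17 rose with them (1.37, adjusted p = 0.0467). The list was called by camera (adjusted p = 5.58e-11), and its adjusted p was 0.769 with an estimated correlation. Its mean log2 level was below the average of the 6 libraries in each CS library (-0.67 to -0.32) and above it in each SS-31H_CS library (0.12 to 1.06).

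**Figure D3:**
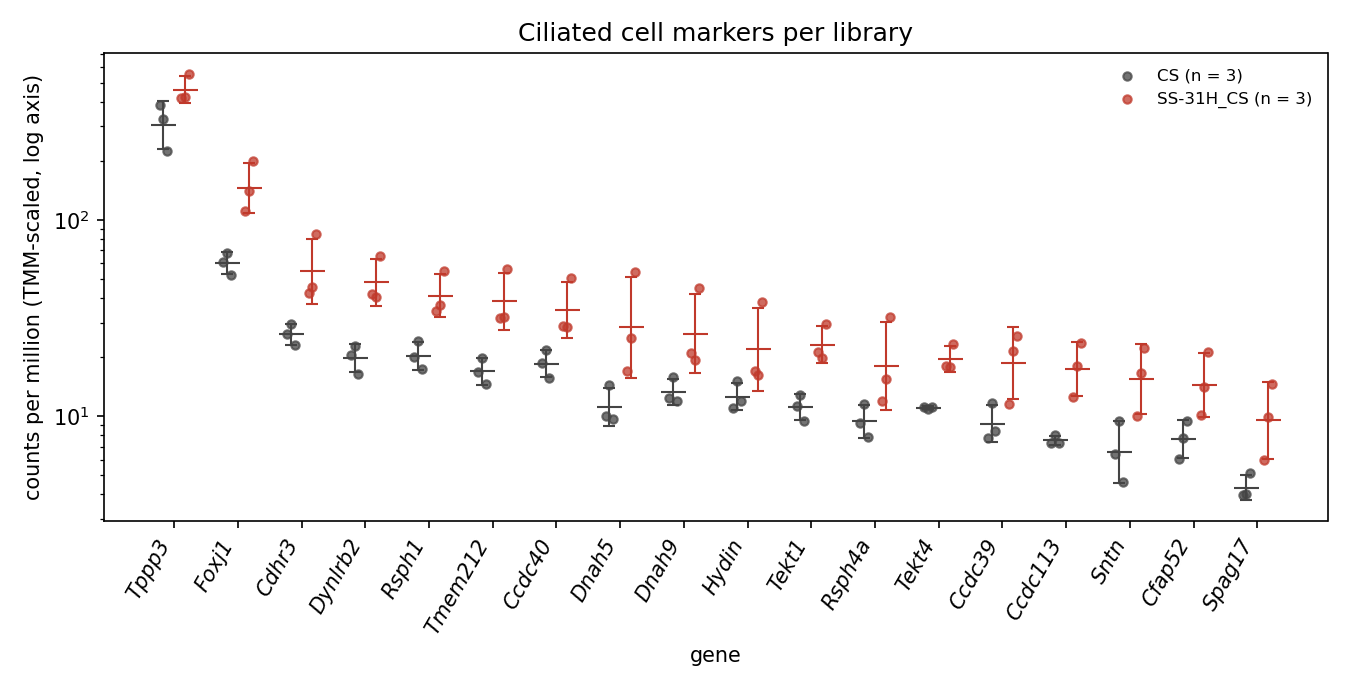
CPM (TMM-scaled, log axis) of the 18 ciliated cell markers in the 3 CS libraries (grey) and the 3 SS-31H_CS libraries (red); points are libraries, and the line and bars are the mean and SD on the log2 scale. Foxj1 lies between 52.6 and 67.9 CPM in CS and between 111 and 199 CPM in SS-31H_CS.

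Club cells, the secretory cells of the small airways, gave a similar direction: 4 of 13 markers rose adjusted over the list alone and 1 over all genes, with a median of 0.73 (1.65-fold). Scgb3a2, a secretoglobin (ENSMUSG00000038791, chromosome 18, 43764289 to 43767399), rose from 288 ± 33.1 to 782 ± 155 CPM (1.44, SE 0.18, adjusted p = 0.0467). Chad (1.58), Gabrp (1.0; 0.59 without SS-31H_CS replicate 3) and Cbr2 (0.77; 0.48 without it) rose adjusted over the list alone. Camera called the list (adjusted p = 0.00784), and the adjusted p was 0.788 with an estimated correlation. The median was 0.46 without SS-31H_CS replicate 3, and the number that rose was 2 without CS replicate 1, CS replicate 2 or CS replicate 3 and 8 without SS-31H_CS replicate 2. In a list of 13 other airway epithelium genes, chosen after the ciliated result was seen, the mean log2 difference was 0.50 (SE 0.20).

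Some alveolar macrophage genes fell. Lpl, lipoprotein lipase (ENSMUSG00000015568, chromosome 8, 68880491 to 68907448), fell from 277 ± 4.92 to 122 ± 0.933 CPM (-1.19, SE 0.10, adjusted p = 0.00900). Of the 15 alveolar macrophage markers, 6 fell adjusted over the list alone and 1, Lpl, over all genes. The number over the list alone was 4 without CS replicate 1, CS replicate 2, SS-31H_CS replicate 2 or SS-31H_CS replicate 3. The scavenger receptor gene Marco (25.7 ± 4.04 to 12.6 ± 2.25 CPM, -1.03), the chitinase-like gene Chil3 (1417 ± 204 to 634 ± 187 CPM, -1.16) and the mannose receptor gene Mrc1 (-0.71) were among the 6. The list was called by camera (adjusted p = 0.0019; 0.769 with an estimated correlation), with a median of -0.26. Cd5l, a secreted macrophage protein outside the list, fell from 4.48 ± 0.782 to 0.696 ± 0.180 CPM (-2.67, SE 0.31, adjusted p = 0.0467). Of 14 tested genes of smoke- and lipid-laden macrophages, 2 fell adjusted over the list alone and 0 over all genes (5 at an unadjusted p under 0.05, 2 by DESeq2): Gpnmb (-0.86) and the lipid receptor gene Cd36 (-0.46). That list was called too (median -0.42, adjusted p = 0.00808; 0.769 with an estimated correlation). Mmp12, the macrophage elastase, was at 4.31 ± 2.32 CPM in CS and 4.35 ± 0.328 CPM in SS-31H_CS (0.01, adjusted p = 0.991). Its sign turned without CS replicate 3 (-0.34) or SS-31H_CS replicate 1 (-0.06). Among 12 monocyte and interstitial macrophage markers 0 passed adjusted over the list alone or over all genes by edgeR's test (4 at an unadjusted p under 0.05, 0 by DESeq2), and the list was not called (adjusted p = 0.923), its median (0.17) and mean (-0.02) differing in sign.

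Adjusted over the list alone, 9 of 22 extracellular matrix genes fell and 3 rose, with 0 over all genes (13 at an unadjusted p under 0.05, 7 by DESeq2). The fibronectin gene Fn1 went from 882 ± 59.8 to 489 ± 114 CPM (-0.85, adjusted p = 0.0926 over all genes), the elastin gene Eln from 467 ± 183 to 187 ± 40.4 CPM (-1.32) and the elastin cross-linking gene Loxl1 from 158 ± 43.0 to 85.3 ± 9.85 CPM (-0.89). Camera called the list (median -0.27, adjusted p = 0.0269; 0.769 with an estimated correlation). The call was lost without SS-31H_CS replicate 1 (adjusted p = 0.113, in a range of 0.0115 to 0.113 over single libraries left out), and the number that passed, 12, was 5 without SS-31H_CS replicate 2 or SS-31H_CS replicate 3. Of 20 proteases and inhibitors, 4 fell adjusted over the list alone and 0 over all genes (9 at an unadjusted p under 0.05, 5 by DESeq2): Mmp19 (31.2 ± 4.64 to 14.7 ± 1.72 CPM, -1.08), Adamts4 (-3.12), the protease inhibitor gene Serpina3n (-1.96; -0.97 without CS replicate 3) and Mmp14 (-0.57). That list was called (median -0.42, adjusted p = 0.00721; 0.769 with an estimated correlation), and 7 members passed without CS replicate 2. Adamts4 was at 3.55 ± 1.97 CPM in CS and near the floor in SS-31H_CS, at 0.402 ± 0.341 CPM (3, 13 and 4 counts). Its log2 fold change ran from -4.05 to -2.58 over single libraries left out. Mmp9 was at 192 ± 23.3 CPM in CS and 131 ± 103 CPM in SS-31H_CS (-0.56, adjusted p = 0.581). The Mmp9 value was -1.39 without SS-31H_CS replicate 1 and -0.15 without SS-31H_CS replicate 3.

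Single genes that fell over all genes outside the lists included Has1 (ENSMUSG00000003665, chromosome 17, 17843323 to 17855205), from 13.7 ± 4.52 to 2.11 ± 0.198 CPM (-2.69, SE 0.29, adjusted p = 0.0337), and Thbs1, thrombospondin 1, from 356 ± 51.5 to 151 ± 17.4 CPM (-1.23, adjusted p = 0.0467). The noradrenaline transporter gene Slc6a2 fell from 164 ± 15 to 63.5 ± 13.8 CPM (-1.37). The interleukin 18 receptor gene Il18r1 fell from 161 ± 24.8 to 78.2 ± 6.64 CPM (-1.04). Fam107a fell from 43.3 ± 19.7 to 8.75 ± 1.64 CPM (-2.31, adjusted p = 0.0496), and the PAF1 complex gene Leo1 (-1.11) and Vstm4 (-1.10) fell as well. The remaining 6 changed genes lie outside the naming rule and were chosen after their values were seen: Tbx1 (1.16) and Cys1 (1.08) rose, and Adgrl3 (-0.96), Rhoj (-0.87), Cacna1d (-0.83) and Ahcyl2 (-0.72) fell. Of the 26 changed genes, 10 have exons that overlap exons of another annotated gene on either strand. The overlap covers 10% or more of the exon length in Dbp (18.0%), Bhlhe41 (19.0%) and Ccdc17 (33.1%), each with a gene on the other strand. Only for Cfap43 did the overlapping genes lie on the same strand. The strand setting of the counting is unstated, so an effect on the counts could not be checked.

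Genes that respond to glucocorticoids were lower as a group: 10 of 13 fell adjusted over the list alone and 0 over all genes (10 at an unadjusted p under 0.05, 8 by DESeq2), and 13 of 13 had a negative log2 fold change (median -1.12). Sgk1 went from 227 ± 36.9 to 118 ± 15.9 CPM (-0.95, adjusted p = 0.0728 over all genes). The chaperone gene Fkbp5 went from 180 ± 144 to 36.4 ± 4.40 CPM (-2.30), and the cell cycle inhibitor gene Cdkn1a from 223 ± 185 to 44.2 ± 0.0975 CPM (-2.34). Klf9 was lower by a smaller amount (-0.62). Camera called the list (adjusted p = 6.42e-07; 0.769 with an estimated correlation). CS replicate 3 stood highest, with a mean log2 level of 1.34 against 0.20 and 0.14 in the other CS libraries. Without it 10 genes still passed adjusted over the list alone, with a median of -0.63. Fkbp5 (-1.42, adjusted p = 0.0474) and Cdkn1a (-1.41, adjusted p = 0.0241) then passed over all genes. Over all alternatives their adjusted p ran from 0.00311 to 0.320 and from 0.00311 to 0.312. The same library was low in B and plasma cell (-1.33), T and NK cell (-1.16) and erythroid (-1.77) markers, on the same scale.

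**Figure D4:**
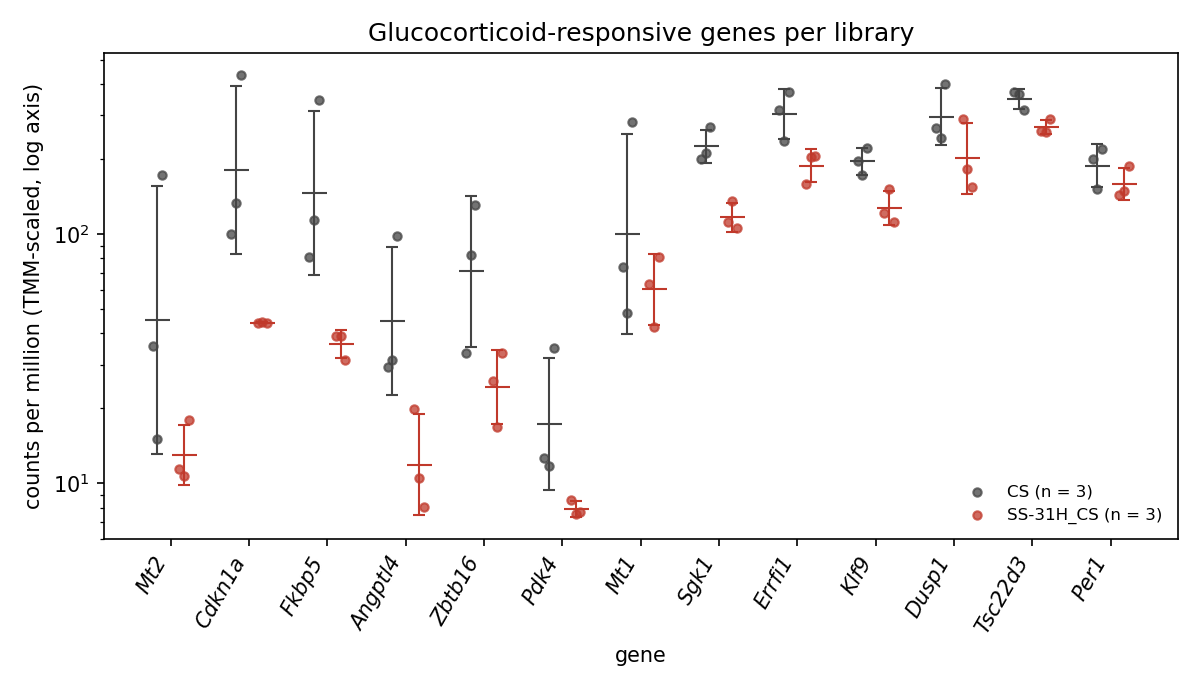
CPM (TMM-scaled, log axis) of the 13 glucocorticoid-responsive genes in the 3 CS libraries (grey) and the 3 SS-31H_CS libraries (red); points are libraries, and the line and bars are the mean and SD on the log2 scale. The highest CS point of Fkbp5 (345 CPM) and of Cdkn1a (436 CPM) is CS replicate 3.

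Genes induced by smoke constituents through the aryl hydrocarbon receptor were lower in part. The smoke schedule is given for CS only, so a difference in smoke exposure between the groups could not be checked. Of 8 tested, 3 fell adjusted over the list alone and 0 over all genes (4 at an unadjusted p under 0.05, 2 by DESeq2): the quinone reductase gene Nqo1 (18.4 ± 2.01 to 7.32 ± 1.71 CPM, -1.33, adjusted p = 0.0606 over all genes), Aldh3a1 (58.8 ± 20.7 to 26.5 ± 9.93 CPM, -1.15) and Cyp1a1 (206 ± 159 to 30.4 ± 16.6 CPM, -2.76, adjusted p = 0.165 over all genes). Cyp1a1 was at 291 and 305 CPM in CS replicates 1 and 2 and at 23.4 CPM in CS replicate 3, inside the SS-31H_CS range of 14.1 to 47.2 CPM. Cyp1b1 had a log2 fold change of -0.81 (adjusted p = 0.399; -0.47 without CS replicate 1 and -1.25 without SS-31H_CS replicate 3). The list was called (median -0.59, adjusted p = 0.0250; 0.788 with an estimated correlation). The call was lost without CS replicate 1 (adjusted p = 0.0731), CS replicate 2 (0.0650) or SS-31H_CS replicate 1 (0.121), in a range of 0.00115 to 0.121 over single libraries left out, and without any of these 3 libraries 1 gene passed.

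Of 23 tested NRF2 targets, the antioxidant response genes, 1 fell adjusted over the list alone (Nqo1) and 0 over all genes (5 at an unadjusted p under 0.05, 2 by DESeq2). The list was called (median -0.20, adjusted p = 0.0255; 0.788 with an estimated correlation), but not without CS replicate 3 (adjusted p = 0.133) or SS-31H_CS replicate 2 (0.244), in a range of 0.00124 to 0.244 over single libraries left out. Hmox1, heme oxygenase 1, was at 45.2 ± 16.5 and 39.9 ± 2.18 CPM (-0.18, adjusted p = 0.702; 0.14 without CS replicate 3), and Nfe2l2, which encodes NRF2 itself, had a log2 fold change of -0.10 (adjusted p = 0.689; 0.00 without CS replicate 3). Among 20 antioxidant enzymes 0 passed adjusted over the list alone or over all genes (2 at an unadjusted p under 0.05, 0 by DESeq2), with a median of 0.00 and a camera adjusted p of 0.831. Sod2, the mitochondrial superoxide dismutase, had a log2 fold change of 0.08 (SE 0.19, adjusted p = 0.850; -0.09 without CS replicate 2).

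Of 9 MHC class II genes, 5 rose adjusted over the list alone and 0 over all genes (6 at an unadjusted p under 0.05, 3 by DESeq2), and 9 of 9 had a positive log2 fold change (median 0.74). H2-Aa went from 352 ± 100 to 601 ± 114 CPM (0.77, adjusted p = 0.157 over all genes), and the invariant chain gene Cd74 from 1077 ± 181 to 1583 ± 317 CPM (0.56). The list was called (adjusted p = 0.00287; 0.788 with an estimated correlation), and 0 genes passed adjusted over the list alone without CS replicate 1, CS replicate 3, SS-31H_CS replicate 1 or SS-31H_CS replicate 2. CS replicate 3 had the lowest mean log2 level of these genes (-0.95). Of 10 dendritic cell markers, 4 rose adjusted over the list alone and 0 over all genes (4 at an unadjusted p under 0.05, 3 by DESeq2): the integrin gene Itgae (1.80), the chemokine receptor gene Xcr1 (1.81), Siglech (1.38) and the chemokine gene Ccl22 (1.82; 1.28 without SS-31H_CS replicate 2). The dendritic cell list was called (median 0.44, adjusted p = 0.00808, and 0.769 with an estimated correlation), and 2 genes passed without CS replicate 2, CS replicate 3 or SS-31H_CS replicate 2. Xcr1 and Siglech were at low levels. Xcr1 went from 0.933 ± 0.213 to 3.29 ± 1.215 CPM and Siglech from 0.749 ± 0.230 to 1.97 ± 0.430 CPM. Ccl22 was at 4.54 CPM in CS replicate 1 and 4.55 CPM in SS-31H_CS replicate 1. B and plasma cell markers were called higher (median 0.67, adjusted p = 0.00808; 0.788 with an estimated correlation; 0.0741 without SS-31H_CS replicate 2, in a range of 2.93e-05 to 0.0741 over single libraries left out), with 0 of 21 genes past the threshold adjusted over the list alone or over all genes by edgeR's test (2 at an unadjusted p under 0.05, 0 by DESeq2). The B and plasma cell markers had a mean log2 level of -1.33 in CS replicate 3. The other CS libraries were at -0.15 and 0.38, and the SS-31H_CS libraries at 0.11 to 0.64. T and NK cell markers (0 of 19 genes, 0 at an unadjusted p under 0.05 and 0 by DESeq2, median 0.48, adjusted p = 0.0503) and erythroid markers (0 of 8, 1 unadjusted and 0 by DESeq2, median 0.58, adjusted p = 0.0503) were not called.

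**Figure D5:**
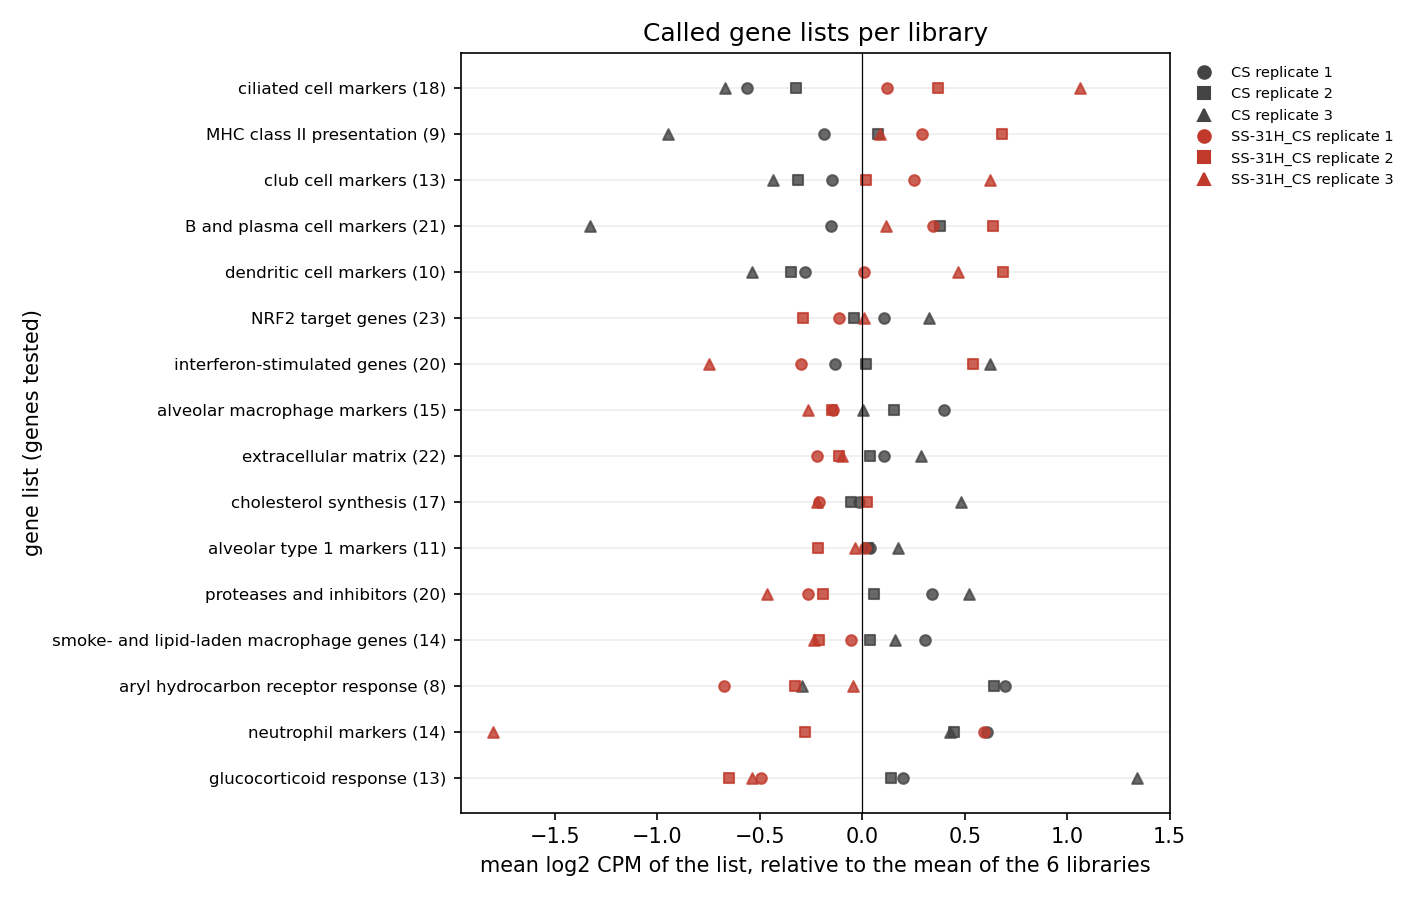
Mean log2 CPM of each of the 16 called gene lists in each library, relative to the mean of the 6 libraries; the number of genes tested is in brackets, CS libraries are grey and SS-31H_CS libraries red, and the shape of a point is its replicate number. The ciliated cell markers lie between -0.67 and -0.32 in CS and between 0.12 and 1.06 in SS-31H_CS, and the neutrophil markers at -1.80 in SS-31H_CS replicate 3.

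Of 26 tested cytokines and chemokines, 0 passed adjusted over the list alone or over all genes by edgeR's quasi-likelihood test (6 at an unadjusted p under 0.05, 2 by DESeq2), and camera did not call the list (adjusted p = 0.222). The median log2 fold change was -0.15, the mean 0.00. Il1b was at 96.5 ± 34.0 and 44.2 ± 28.5 CPM (-1.13, adjusted p = 0.236; -1.78 without SS-31H_CS replicate 1), Cxcl2 at 11.8 ± 15 and 0.744 ± 0.576 CPM (-3.98, adjusted p = 0.145; -2.10 without CS replicate 1), and Ccl2 at -0.90 on the log2 scale (adjusted p = 0.480; 0.00 without CS replicate 3). Cxcl5 (1.9), Cxcl1 (0.98) and Tnf (0.52) turned to -0.51, -0.44 and -0.41 without SS-31H_CS replicate 2. Il6 had 40 counts in all and was not tested. By edgeR's test 0 of 20 NF-kB and MAPK signalling genes passed adjusted over the list alone or over all genes (1 unadjusted, 1 by DESeq2; list adjusted p = 0.412), 0 of 12 inflammasome genes (3 unadjusted, 1 by DESeq2; 0.515, with a median of 0.06 and a mean of -0.11) and 0 of 12 acute phase and antimicrobial genes (3 unadjusted, 0 by DESeq2; 0.412). Neutrophil markers were called lower (median -0.81, adjusted p = 0.0112; 0.788 with an estimated correlation), with 1 of 14, the decoy receptor gene Il1r2 (-3.09), past the threshold adjusted over the list alone and 0 over all genes (2 at an unadjusted p under 0.05, 1 by DESeq2). That call was lost without SS-31H_CS replicate 3 (adjusted p = 0.0881, in a range of 3.37e-05 to 0.0881 over single libraries left out), whose mean log2 level of these markers was -1.80. Interferon-stimulated genes were called lower (median -0.22, adjusted p = 0.0460; 0.848 with an estimated correlation), with 0 of 20 genes past the threshold over the list alone or over all genes (1 unadjusted, 0 by DESeq2), and the call was lost without CS replicate 3 (0.662), SS-31H_CS replicate 1 (0.208) or SS-31H_CS replicate 3 (0.650), in a range of 2.37e-06 to 0.662 over single libraries left out.

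Mitochondrial genes showed no change that passed the test. The 57 tested nuclear genes of the respiratory chain had a median log2 fold change of 0.00 (camera adjusted p = 0.947), with 0 past the threshold adjusted over the list alone or over all genes by edgeR's test (3 at an unadjusted p under 0.05, 1 by DESeq2). The complex I gene Ndufa6 had the lowest p among them (53.9 ± 1.80 to 71.2 ± 2.61 CPM, 0.40, adjusted p = 0.107). All 11 tested genes of the mitochondrial genome had a positive log2 fold change (median 0.28), but 0 passed adjusted over the list alone or over all genes (0 unadjusted, 0 by DESeq2) and the list was not called (adjusted p = 0.0503; 0.788 with an estimated correlation). Their mean log2 level was 0.40 in SS-31H_CS replicate 3, 0.12 and -0.14 in the other SS-31H_CS libraries and -0.20 to -0.05 in CS. Without SS-31H_CS replicate 3 mt-Co1 went from 0.33 to 0.15 and mt-Nd4 from 0.33 to 0.07. Levels of the mitochondrial genes were very unequal, with CS means of 6281 CPM for mt-Co1, 11.2 for mt-Co2 and 0.752 for mt-Nd3. Whether reads of the low ones were lost in counting was not tested. Among genes of mitochondrial dynamics, mitophagy and biogenesis 0 of 22 passed adjusted over the list alone or over all genes (1 unadjusted, 0 by DESeq2; median -0.01, mean 0.01, adjusted p = 0.757). Dnm1l was at -0.18 (-0.35 without SS-31H_CS replicate 2, -0.03 without SS-31H_CS replicate 1 and -0.11 without CS replicate 3). Mfn2 was at -0.20 (-0.12 without SS-31H_CS replicate 2). Opa1 was at -0.21 (-0.12 without CS replicate 3). Genes for cardiolipin, the inner membrane lipid that SS-31 binds, had 0 of 9 past either threshold (2 unadjusted, 0 by DESeq2; median 0.03, adjusted p = 0.736). NADPH oxidase and reactive oxygen genes had 0 of 11 (3 unadjusted, 2 by DESeq2; median -0.26, adjusted p = 0.332), with Cybb at 99.4 ± 18.4 and 92.9 ± 32.3 CPM (-0.10; 0.16 without SS-31H_CS replicate 3). In simulated data with 3 libraries per group, 5.1% of 1.5-fold and 58.1% of 2-fold changes were found.

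Alveolar type 1 markers were called lower (median -0.32, adjusted p = 0.0460; 0.788 with an estimated correlation), with Col4a3 (-0.45) and Akap5 (-0.56) falling and Igfbp2 (0.65) rising adjusted over the list alone, out of 11, and 0 over all genes (6 unadjusted, 3 by DESeq2). This call was lost without CS replicate 3 (0.1) or SS-31H_CS replicate 2 (0.172), in a range of 0.0317 to 0.172 over single libraries left out. Alveolar type 2 markers were not called (0 of 13 by edgeR's test, 4 unadjusted, 2 by DESeq2; adjusted p = 0.332), and the surfactant gene Sftpc was at 13300 ± 850 and 14230 ± 2386 CPM (0.10, adjusted p = 0.809; 0.00 without SS-31H_CS replicate 3). Cholesterol synthesis genes were called lower (median -0.30, adjusted p = 0.00808; 0.788 with an estimated correlation; 0.157 without CS replicate 3, in a range of 0.00111 to 0.157 over single libraries left out), with 0 of 17 past the threshold over the list alone or over all genes by edgeR's test (3 unadjusted, 1 by DESeq2). Mucus and goblet cell genes were not called (0 of 8, 4 unadjusted, 0 by DESeq2; median 1.24, adjusted p = 0.0868): Muc5ac was at 75.9 CPM in SS-31H_CS replicate 2 and at 1.03 to 1.53 CPM in the other 5 libraries, and its log2 fold change of 4.43 (adjusted p = 0.203) was 0.14 without that library. In the fibroblast list, which was not called (adjusted p = 0.244), Pdgfra (-0.76) fell and Mfap5 (1.02) rose adjusted over the list alone.

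Of the 46 lists tested, camera with the preset correlation called 16, 5 higher and 11 lower. With an estimated correlation it called 0 (1 list at an unadjusted p under 0.05), fry called 0 in a single direction and 14 for change in either direction, and other splits of the 6 libraries into 3 and 3 gave 10 to 21 called lists with the preset correlation, a number not particular to the real grouping. Over all genes, limma voom called 4 members of the clock list, 1 alveolar macrophage marker and 0 members of each other list.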

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

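Leaving out replicate 3 of both groups together, and recounting single lists without each library, were chosen after the data had been seen; the other alternatives were planned. The number of changed genes (26; 12 higher, 14 lower) stayed within 1.5 times under RLE size factors (24), a filter at 1 CPM (27), robust dispersion (38 in all, 17 lower but 21 higher), a log2 fold change of at least 1 (22) and without replicate 3 of both groups (36, of which 17 were among the 26). It was 12 with library size alone (6 higher, 6 lower), 648 with no low-count filter (391, 257), 948 by DESeq2 (540, 408), 6 by voom (3, 3), 6 on log2(FPKM + 1) (5, 1), 5 on log2(FPKM + 0.1) (4, 1), 4 on log2(FPKM + 1) with no filter (3, 1) and 299 at an adjusted p under 0.1 (193, 106). With no filter and by DESeq2 all 26 were called. In simulated data their false calls were 36.3% and 19.6% against 8.8%, and they found 69.9% and 69.5% of 2-fold changes against 58.1%. Otherwise the cause was not tested. With the replicate number as a block edgeR's test gave 0 genes (0 higher, 0 lower, 2682 at an unadjusted p under 0.05). In simulated data the block fit found 54.2% of 2-fold and 92.4% of 4-fold changes, against 58.1% and 93.6% without the block. Its false share there was 11.3%. Why all 26 genes were lost with the block was not tested. Deviations from the group means showed no sign of pairing (correlations of 0.01, 0.04 and -0.06 between libraries of one number). Such correlations cannot exclude pairing, and the labels do not say what the numbers mark. Over single libraries left out the count ran from 1 to 15 (1 to 5 higher, 0 to 10 lower), with fewer samples.

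The 16 called lists were 0 with an estimated correlation and 0 by fry, 15 to 18 over single libraries left out, and 16 to 22 under the other alternatives. The 20 named genes that changed kept their direction in all 400 alternative values, 195 past the threshold and 205 not. The kept direction is not separate support. These genes were named for groups that do not overlap, which leaves little room for a turned sign. The alternatives that change only the threshold reuse the main estimate, and an adjusted p under 0.1 is then met by every one of these genes. Of the 137 other named genes, 63 passed under at least 1 alternative, a count that includes genes reaching only an adjusted p under 0.1. Without replicate 3 of both groups the interferon list turned to higher (adjusted p = 0.304), and the sign turned in Ccl2 (0.14), Hmox1 (0.19), Sftpc (-0.02), Cybb (0.02), Mmp12 (-0.29) and Isg15 (0.26). Over single libraries left out the sign turned in Cxcl5 (-0.51 to 2.42), Cxcl1 (-0.44 to 1.51), Tnf (-0.41 to 0.83), Ltf (-0.34 to 1.31), Nfe2l2 (-0.17 to 0.00), Hmox1 (-0.38 to 0.14), Sftpc (0.00 to 0.23), Sod2 (-0.09 to 0.29), Cybb (-0.29 to 0.16) and Mmp12 (-0.34 to 0.45); the cause was not tested. In simulated data with 3 libraries per group, 58.1% of 2-fold and 5.1% of 1.5-fold changes were found; neither depth nor number was varied.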

Other observations

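The tests of the hour of collection and of single libraries, and the patterns they weigh, were chosen only after the results were seen; the test on other airway genes and the counts of other splits were set out before their values were known.

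Some differences lay in a single library. SS-31H_CS replicate 2 was high in mucus, chemokine and antimicrobial transcripts: the trefoil gene Tff2 was at 84.5 CPM against 0.941 to 4.67 CPM in the other 5 libraries, Pigr, the transporter of secreted antibodies, at 291 CPM against 35.5 to 75.4 CPM, and Ltf, lactoferrin, at 453 CPM against 47.9 to 149 CPM. CS replicate 3 was high in the keratin genes Krt8 (999 CPM against 222 to 324 CPM elsewhere) and Krt19 (1120 against 237 to 307 CPM) and low in hemoglobin Hba-a2 (5.12 CPM against 16.7 to 42.2 CPM). None of these 6 genes passed edgeR's test between the groups (adjusted p from 0.192 to 0.518).

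The remaining lists were not called by camera. Fatty acid synthesis genes had a median log2 fold change of -0.12 (adjusted p = 0.0503), with 1 of 15, Fasn, the fatty acid synthase gene (961 ± 84.8 to 631 ± 55.1 CPM, n = 3 each), lower adjusted over the list alone and 0 over all genes by edgeR's test (3 unadjusted, 1 by DESeq2). Endothelial markers had a median of -0.19 (adjusted p = 0.0551), immediate-early genes -0.16 (0.336), cell cycle genes -0.04 (mean 0.01; 0.568) and smooth muscle and pericyte markers -0.01 (mean 0.11; 0.677). In the mast cell, basophil and eosinophil list (median 0.59, adjusted p = 0.431) the transcription factor gene Gata2, which endothelium also expresses, fell adjusted over the list alone (-0.84), and among apoptosis regulators (median -0.08, adjusted p = 0.222) the death receptor gene Fas did (-0.70).

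Of the 18 clock genes, a list set before the data were examined, 14 passed adjusted over the list alone, 9 higher and 5 lower. A single library as the whole cause is argued against, since 12 or more of the 14 still passed with any 1 left out. A candidate explanation is that the lungs of the groups were taken at different hours, since clock transcripts follow the time of day. The 9 higher and 5 lower genes are the pattern itself and say nothing for or against it. The labels give no hour, so lungs of the 2 groups taken at different hours and an effect of SS-31 on the clock cannot be told apart.

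The rise of ciliated cell markers (mean log2 difference 1.04, SE 0.30) was not due to a single library alone, since the median stayed at 0.81 or more with any 1 left out. The pieces of lung sequenced may have held more conducting airway in SS-31H_CS. Other airway epithelium genes, tested for this, had a mean log2 difference of 0.50 (SE 0.20), close to 0.52, which is 0.5 times the ciliated value and the bound set for this explanation. More airway tissue in the sample and an effect of SS-31 on airway epithelium cannot be told apart, because the value lies within its error of the bound.

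The fall of glucocorticoid-responsive genes was largest against CS replicate 3, but 10 of the genes that passed adjusted over the list alone still passed without it, with the median at -0.63 instead of -1.12, so that library is not the whole cause, though it sets much of the size. Glucocorticoid levels follow the time of day, so lungs of the 2 groups taken at different hours are a candidate explanation here too. That 13 of 13 genes tested had lower values in SS-31H_CS is the pattern itself and says nothing for or against it. Without an hour in the labels this and an effect of SS-31 cannot be told apart. The same limit holds for any other gene that follows the time of day, since the hour is unknown for all 6 libraries.

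The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 26 changed genes, 12 higher and 14 lower, and 1 of the 10 splits, the real one, gave as many in each count; the highest of the other splits was 0 in each by edgeR's test (869 genes at an unadjusted p under 0.05, against 3081). Each other split mixes libraries of both groups, so any difference between the real groups adds to the spread within the split groups and lowers the count. The 0 of the other splits therefore does not show what chance alone gives. For called lists 5 of the 10 splits gave as many as the real 16, and the highest other gave 21.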
